A study of Mus musculus with 12 samples.

How the data were processed

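The deposited table holds 45101 probe sets, 64 of them controls, on 12 arrays. Its intensity values were made by the authors with MAS5, per the submitters' processing notes. The MAS5 version and the target of its scaling are not given in the sources used here. From the values, the deposited table is linear signal intensity from 0.0377 to 31317.3, and each array has the same trimmed mean of 249.9 over the middle 96% of its probe sets. That scaling was kept. Group, genotype and surgery of each array were taken from the labels.

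Values were taken as log2(signal + 15), where 15 is the 20th percentile of all signals rounded to a whole number. A probe set was tested if its signal was over its array's 40th percentile in at least 3 of 12 arrays (30326 probe sets passed). Names came from the platform annotation, which gave 1 gene to 34958 probe sets, several to 932 and none to 9160. Of the 34958, 34754 matched the Entrez gene table and 204 did not. Each gene was represented by the probe set with the highest mean log2 value, which left 14322 genes. Of these, 6425 had several probe sets past the filter. Probe sets without a single name were tested in a fit of all probe sets and are otherwise left out. Some genes of the fixed lists are not analysed here.

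Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) in 1 model of all 12 arrays with a mean for each of the 4 groups, which leaves 8 residual degrees of freedom. The 5 comparisons were ischemic minus sham in wild type, the same in TLR4 null, the difference of these responses (interaction), and TLR4 null minus wild type in sham and in ischemic kidneys. Tests were two-sided, p was adjusted by Benjamini and Hochberg over all genes of a comparison, and genes under an adjusted p of 0.05 were called. Gene lists, 29 fixed before the files were seen, were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 27 lists with at least 4 measured members. The lymphocyte and erythroid lists had 3 each and were not tested. List members were also adjusted over their list alone. Every Tlr4 probe set was tested in a fit of all probe sets.

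The rule for genes named in the text was fixed beforehand. It took the 8 largest rises and 8 largest falls among called genes whose groups do not overlap, up to 4 measured members of each list with the smallest p, and Tlr4 and 13 other genes given in both genotypes. Since no interaction passed, it took the 5 genes with the smallest p there. Predicted genes without a full name were skipped. Genes named outside this rule, such as all 19 shared by the genotype comparisons and those given for gene families, were chosen after their values were seen.

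Array quality (median signal, Gapdh and actin 3' over 5' ratios, 18S control probe sets, fat score) was tested with exact permutation tests in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9. The gene and list steps were tested on simulated data with 200 changed genes. In the wild-type comparison 20.9%, 70.1% and 97.0% of changes of 0.5, 1 and 2 log2 units were recovered, with 6 false among 131 calls. For the interaction there were 5 false among 104 calls. A list shifted by 0.5 was called and 0 of 20 unshifted lists were. The simulated genes varied independently of each other, so this could not show false list calls from genes that vary together. They were drawn with spreads that limma had already pulled toward each other, so recovery may be overstated.

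Alternatives fixed beforehand were quantile and median normalization, pseudocounts of 1 and 60, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, leaving out probe sets with the suffix _x_at or _s_at, eBayes without the trend, array weights, only the arrays of the 2 groups compared, an ordinary equal-variance test per gene, a block for the replicate number, leaving out each array, and for lists the estimated correlation. The fat score as a covariate, the 13 gene families named by symbol, the collagen score and the count of calls that hold without each array were added after the data were seen. No alignment or genome was used.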

Results

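Gene expression was measured in whole kidneys of 8-week-old male mice of the C57BL/10 strain (wild type) and of its substrain C57BL/10ScNJ, which lacks Toll-like receptor 4 (TLR4 null). TLR4 is a receptor of innate immunity that binds bacterial lipopolysaccharide and has been proposed to bind molecules released from damaged tissue. In each genotype, 3 kidneys were clamped at the pedicle for 23 min after removal of the other kidney and collected at 4 h of reperfusion, and 3 came from sham-operated mice. The 12 kidneys were hybridised to 12 arrays, and the labels call the arrays of a group biological replicates. Median signals per array ran from 61.2 to 77.4, and log2 values correlated across genes at r = 0.963 to 0.979 between arrays of a group and at r = 0.933 to 0.976 between arrays of different groups. The number of arrays, 3 per group, limits the precision of every value. Fold changes are differences of log2(signal + 15), which understates the folds of genes with low signals. The comparisons ask how the kidney responds to ischemia and reperfusion in each genotype, whether the response differs without TLR4, and how the genotypes differ within each surgery.

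Tlr4 itself was measured first, because it checks the genotype labels. Which of its 4 probe sets lie in the deleted part was not determined here. The check rests on the probe set with the largest difference between the genotypes, and picking it by that difference weakens the check. That probe set, the left one in the figure, gave signals of 65.6 to 120.4 on the 6 wild-type arrays and of 0.901 to 3.38 on the 6 TLR4 null arrays. The difference was -2.43 ± 0.24 on the log2 scale in sham kidneys (limma, adjusted p = 0.00138 over all probe sets) and -2.81 ± 0.24 in ischemic kidneys (adjusted p = 0.000349). The probe set that stands for the gene in the gene tests (the right one) gave 72.9 to 134.8 in wild type and 6.33 to 60.4 in TLR4 null kidneys, also without overlap. It did not pass the limma test (adjusted p = 0.683 in sham and 0.444 in ischemic kidneys). The other 2 probe sets stayed under a signal of 42 on every array. Ischemia did not move the first of these probe sets past the test in wild type (0.38 ± 0.24, adjusted p = 0.416).

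**Figure D1:**
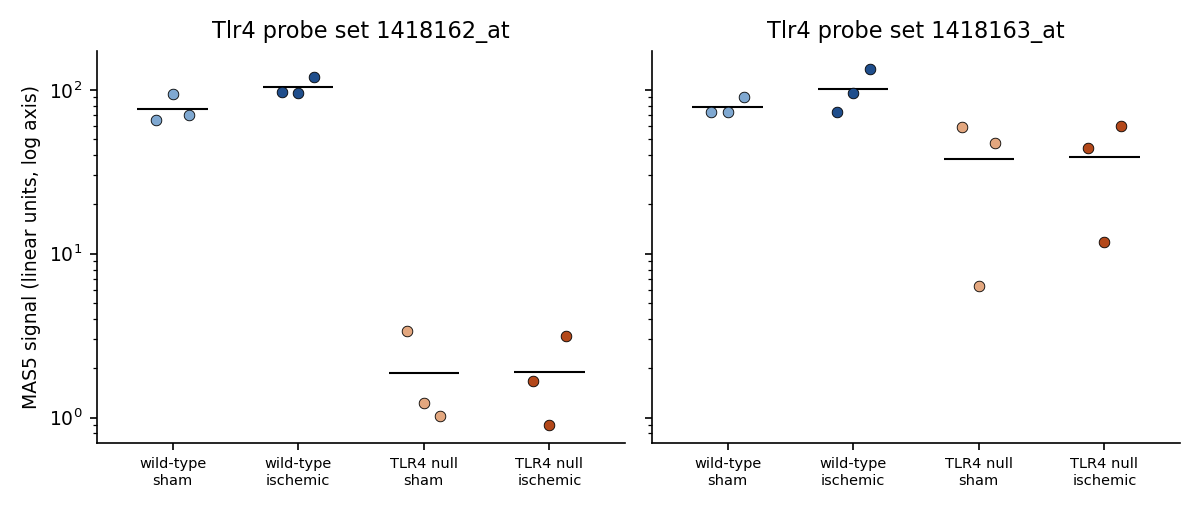
Signal of 2 Tlr4 probe sets (linear MAS5 units, log axis) on each of the 12 arrays by group, where points are arrays and lines are group means of 3 arrays. The left probe set lies between 65.6 and 120.4 in wild type and at 3.38 or below in TLR4 null kidneys.

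In wild-type kidneys the 8 largest rises after ischemia included Krt20, Hspa1a and the early transcription factors Atf3, Fos, Egr1, Maff and Jun. Krt20, an intermediate filament keratin, rose by a log2 fold change of 5.66 ± 0.40 (SE, 3 arrays per group here and below, limma adjusted p = 1.91e-07), from a signal of 69.5 ± 8.22 (SD) in sham to 4351 ± 1112 in ischemic kidneys. Atf3, a stress-induced transcription factor, rose by 5.12 ± 0.33, and the AP-1 subunits Fos and Jun rose by 4.80 ± 0.34 and 3.71 ± 0.34. Hspa1a, the inducible 70-kDa heat shock protein, rose by 4.79 ± 0.37, from 432 ± 92.0 to 12165 ± 700. The zinc finger factor Egr1 rose by 4.61 ± 0.28, the small Maf factor Maff by 4.36 ± 0.41 and Sprr2f, a small proline-rich protein, by 4.15 ± 0.40. The largest falls were in Upp2, a uridine phosphorylase (-3.11 ± 0.21), Igfbp1, a binding protein of insulin-like growth factors (-2.29 ± 0.40), Apela, a ligand of the apelin receptor (-2.27 ± 0.15), the transporter Slc16a9 (-2.22 ± 0.18), Smim5 (-2.13 ± 0.38), Wscd2 (-2.07 ± 0.40), Cep128 (-2.03 ± 0.31) and G6pc, the catalytic subunit of glucose-6-phosphatase (-1.95 ± 0.13). Across 14322 genes, 2814 passed an adjusted p of 0.05 in limma, 1313 higher and 1501 lower. Of these, 346 rose and 151 fell at least 2-fold. Median scaling of the arrays changed the split to 1289 higher and 666 lower of 1955, and the median over all genes was -0.09 as deposited and -0.01 with that scaling.

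The early transcription factors moved as a group. Of 23 measured immediate early and AP-1 genes, 22 rose, and 22 rose when adjusted over the list alone, with a median of 2.29. Besides Atf3, Egr1, Fos and Jun these included Klf6 (2.84 ± 0.14) and Ier2 (2.68 ± 0.17). The list passed limma's camera test with a preset correlation (adjusted p = 4.09e-31) and with an estimated one (adjusted p = 0.00733 with an estimated correlation). All 14 measured tubular injury markers had higher means after ischemia, 12 passed over all genes and 14 adjusted over the list alone (median 1.57, camera adjusted p = 9.49e-19, and 0.00733 with an estimated correlation). The epithelial keratin Krt8 rose by 1.91 ± 0.08, the matricellular protein Ccn1 by 3.58 ± 0.25, the receptor Tnfrsf12a by 3.11 ± 0.22 and Lcn2, which encodes the injury marker NGAL, by 2.56 ± 0.25. Havcr1, which encodes the injury marker KIM-1, did not pass (1.33 ± 0.53, adjusted p = 0.0956).

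In wild type, 15 of 16 heat shock proteins rose over all genes and 15 adjusted over the list alone (median 1.80), among them Hsph1 (2.96 ± 0.28), Cryab (1.83 ± 0.15) and Hsp90aa1 (1.43 ± 0.12). The list's camera adjusted p was 8.48e-20, and 0.0454 with an estimated correlation. Of 14 genes of the unfolded protein response, 8 rose (8 adjusted over the list alone), with the transcription factor Ddit3 at 2.32 ± 0.11 and the glutathione-degrading enzyme Chac1 at 2.86 ± 0.18. That list had a camera adjusted p of 6.59e-07, and of 0.0215 with an estimated correlation. Among 19 p53 targets and apoptosis genes, 10 rose and 2 fell (11 and 3 adjusted over the list alone), including Plk3 (2.60 ± 0.13), Gadd45a (2.70 ± 0.20), Mcl1 (1.37 ± 0.09) and Pmaip1 (3.20 ± 0.30), with a camera adjusted p of 6.25e-06 and of 0.0479 with an estimated correlation. Of 12 NRF2 targets, which protect against oxidants, 5 rose and 2 fell (5 and 2 adjusted over the list alone). Srxn1, which repairs oxidised peroxiredoxins, rose by 2.86 ± 0.12, and the heme-degrading enzyme Hmox1 by 2.05 ± 0.52. The NRF2 list passed with the preset correlation (adjusted p = 0.00353) but not otherwise (adjusted p = 0.0792 with an estimated correlation).

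The neutrophil-attracting chemokines Cxcl1 and Cxcl2 rose by 3.15 ± 0.25 and 2.96 ± 0.23, and the monocyte-attracting Ccl2 by 0.73 ± 0.22 (adjusted p = 0.0306), while Cxcl12 fell by 0.62 on the log2 scale. Of 13 chemokines, 7 rose and 1 fell (7 and 1 adjusted over the list alone). Their camera adjusted p of 0.00261 did not hold (adjusted p = 0.0807 with an estimated correlation). The cytokine Il6 rose by 3.26 ± 0.37, the growth factor Hbegf by 2.89 ± 0.16 and Csf1, the growth factor of macrophages, by 1.93 ± 0.15. In all, 7 of 13 measured cytokines and growth factors rose (7 adjusted over the list alone, camera adjusted p = 6.77e-06, and 0.00796 with an estimated correlation). Of 16 NF-kB feedback and target genes, 9 rose (10 rose and 1 fell adjusted over the list alone), among them Nfkbiz (2.18 ± 0.12) and Bcl3 (1.22 ± 0.17), and the list's camera adjusted p was 1.19e-07, and 0.0131 with an estimated correlation. The acute phase and STAT3 list had 9 genes that rose and 2 that fell of 18 (9 and 2 adjusted over the list alone), with Socs3 at 2.53 ± 0.24 and the metallothionein Mt2 at 1.09 ± 0.11. Its camera adjusted p of 2.81e-06 was lost (adjusted p = 0.0928 with an estimated correlation). None of 15 interferon-stimulated genes passed, over all genes or adjusted over the list alone.

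Genes of the endothelial activation and coagulation list rose in 11 of 15 cases (13 adjusted over the list alone, camera adjusted p = 1.38e-12, and 0.00733 with an estimated correlation). Whole kidneys were measured, so the cells in which these genes rose were not determined. The metalloprotease Adamts1 rose by 2.52 ± 0.16, tissue factor (F3) by 2.08 ± 0.14, the endothelial protein C receptor Procr by 1.99 ± 0.23 and the leukocyte adhesion molecule Icam1 by 1.20 ± 0.11. Vcam1 rose by 0.52 ± 0.17 (adjusted p = 0.0487), while the selectins Sele (0.99 ± 0.39, adjusted p = 0.0924) and Selp (0.59 ± 0.22, adjusted p = 0.0732) did not pass. Of 15 endothelial cell markers, 1 rose and 3 fell (1 and 3 adjusted over the list alone). The angiopoietin receptor Tek fell by 1.07 on the log2 scale and endothelial nitric oxide synthase (Nos3) rose by 0.90 ± 0.15. Among 18 Toll-like receptors and adaptors, Cd14 (0.91 ± 0.16) and Tollip (0.46 ± 0.09) rose, both also adjusted over the list alone, and the list's call (adjusted p = 0.0252) was lost (adjusted p = 0.205 with an estimated correlation). Of 12 proposed endogenous TLR4 ligands, 6 rose and 1 fell (6 and 1 adjusted over the list alone), led by Hspa1a, Hspa1b and the matrix protein Tnc (2.14 ± 0.24). Hspa1a and Hspa1b are also among the heat shock proteins, and the call (adjusted p = 4.49e-05) was lost (adjusted p = 0.0718 with an estimated correlation).

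Of 15 genes of fatty acid oxidation and PPARA targets, 10 fell and none rose (11 fell adjusted over the list alone, camera adjusted p = 2.34e-06, and 0.0475 with an estimated correlation), among them Cpt2, an enzyme of fatty acid import into mitochondria (-0.99 ± 0.10), and Pdk4 (-0.77 ± 0.12). Under median scaling this list kept its direction and call. Of 23 proximal tubule transporters, 5 fell and 1, the amino acid transporter Slc6a19 (0.43 ± 0.12), rose (7 and 1 adjusted over the list alone), and the list did not pass. The phosphate transporter Slc34a1 was at 0.13 ± 0.11. Of 17 genes of the loop of Henle, distal tubule and collecting duct, 5 fell (6 adjusted over the list alone), led by the potassium channel Kcnj1 (-1.03 ± 0.09) and the vasopressin receptor Avpr2 (-0.96 ± 0.16). That call (adjusted p = 0.00667) was lost (adjusted p = 0.322 with an estimated correlation). Of 20 hypoxia-inducible genes, 4 rose and 5 fell (5 and 5 adjusted over the list alone), with the glucose transporter Slc2a1 at 0.77 ± 0.09 and the kinase Pdk1 at -0.81 ± 0.12, and none of 7 podocyte genes passed over all genes (2 rose adjusted over the list alone). Of 17 circadian clock genes, 7 rose and 3 fell (7 and 3 adjusted over the list alone), with Nfil3 at 2.18 ± 0.36 and Dbp at 1.18 ± 0.19, and the list's call (adjusted p = 0.043) was lost (adjusted p = 0.205 with an estimated correlation). Among 15 cell cycle genes the replication factor Mcm5 fell (-0.90 ± 0.21), also adjusted over the list alone.

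Among markers of other cells in wild type, 3 of neutrophils and 1 of macrophages rose. Of 9 neutrophil markers, 3 rose (3 adjusted over the list alone), the calprotectin genes S100a8 (1.34 ± 0.21) and S100a9 (1.52 ± 0.22) and Lcn2, which tubular cells also express. The list's call (adjusted p = 0.0352) was lost (adjusted p = 0.205 with an estimated correlation). Of 13 monocyte and macrophage markers, Cd68 rose (0.94 ± 0.19) and Csf1r fell (-0.35 ± 0.09), both also adjusted over the list alone. Only 4 of the 13 had higher means after ischemia (median -0.24), and the list did not pass camera. Fat markers varied between arrays within groups: Adipoq, an adipocyte hormone, gave 201.3 to 1620.3 on the wild-type ischemic arrays and 544.1 to 972.5 on the wild-type sham arrays. None of the 7 fat markers, 3 lymphocyte markers and 3 erythroid markers passed. Among 6 adrenal cortex markers the ferredoxin Fdx1, also a mitochondrial protein of kidney, rose (0.25 ± 0.08), and among 6 muscle markers Tagln rose (0.60 ± 0.18), each also adjusted over the list alone. The ratio of the 3' to the 5' actin control probe sets was 1.92 ± 0.0545 (SD) in wild-type ischemic and 1.76 ± 0.0710 in wild-type sham kidneys, a difference with an exact permutation p of 0.1 (two-sided), the smallest that 3 against 3 allows. Over all 6 ischemic and 6 sham arrays that ratio gave an exact permutation p of 0.0519 (0.364 after adjustment over 14 tests of array quality).

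In TLR4 null kidneys the 8 largest rises after ischemia again included Krt20, Atf3, Fos, Egr1 and Hspa1a. Krt20 rose by 6.80 ± 0.40 (limma adjusted p = 2.92e-08), from a signal of 34.8 ± 29.2 to 4840 ± 1518, Atf3 by 4.45 ± 0.33, Fos by 4.27 ± 0.34 and Egr1 by 4.08 ± 0.28. Cxcl1 rose by 3.91 ± 0.25, the AP-1 subunit Fosl1 by 3.89 ± 0.26, Csrnp1 by 3.81 ± 0.39 and Hspa1a by 3.80 ± 0.37. The largest falls were in Upp2 (-2.64 ± 0.21), Clec2d, a ligand of an inhibitory receptor on natural killer cells (-2.46 ± 0.19), Lrrn1 (-2.40 ± 0.30), G6pc (-2.35 ± 0.13), Slc16a9 (-2.28 ± 0.18), Depp1 (-2.01 ± 0.29), the cytochrome P450 Cyp2b10 (-1.95 ± 0.30) and the mitotic kinesin Kif20b (-1.91 ± 0.32). Of 14322 genes, 3088 passed, 1412 higher and 1676 lower, with 359 rises and 169 falls of at least 2-fold. Median scaling of the arrays changed the split to 1179 higher and 1033 lower of 2212. The median over all genes was -0.07, and groups did not overlap for 4872 of 14322 genes (5627 in wild type), where chance gives 10%. The TLR4 null ischemic arrays stand apart in the 18S 3' control probe set (2114 ± 636 against 406 ± 90.8 in TLR4 null sham kidneys, SD).

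Of 23 immediate early and AP-1 genes, 21 rose over all genes and 21 adjusted over the list alone (median 1.87, camera adjusted p = 2.86e-26, and 0.0113 with an estimated correlation), among them Klf6 (3.05 ± 0.14) and Myc (2.55 ± 0.18). The list's mean log2 value was 10.00, 9.96 and 10.60 in TLR4 null ischemic replicates 1, 2 and 3, against 10.59 to 10.65 in wild-type ischemic kidneys. Egr1 gave 2868.1, 3426.5 and 8458.2 on those TLR4 null arrays. Of 14 tubular injury markers, 13 rose (14 adjusted over the list alone, median 1.84, camera adjusted p = 7.61e-19, and 0.0112 with an estimated correlation), with Krt8 at 2.34 ± 0.08, Lcn2 at 2.98 ± 0.25 and Havcr1 at 1.67 ± 0.53 (adjusted p = 0.0351). Havcr1 was dim and its groups overlapped, with 159.7, 325.9 and 46.0 in ischemic and 11.2 to 56.2 in sham kidneys. In wild type, where Havcr1 did not pass, the groups did not overlap (94.2 to 127.8 and 12.6 to 57.4). Of 16 heat shock proteins, 13 rose (15 adjusted over the list alone, median 1.41), with Cryab at 1.90 ± 0.15 and Hspa1b at 2.39 ± 0.26. That call (adjusted p = 4.83e-13) was lost (adjusted p = 0.0829 with an estimated correlation), and the 3 arrays were far apart, with Hspa1a signals of 6758.4, 2709.6 and 12724.1. Of 12 NRF2 targets, 7 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 5.33e-05, and 0.0272 with an estimated correlation), with Srxn1 at 2.94 ± 0.12 and Hmox1 at 3.44 ± 0.52. The unfolded protein response (8 of 14 rose, 8 adjusted over the list alone, adjusted p = 4.81e-08, and 0.0161 with an estimated correlation) included Ddit3 (2.45 ± 0.11) and Asns (1.89 ± 0.18). Of 19 p53 targets and apoptosis genes, 10 rose (10 rose and 1 fell adjusted over the list alone, adjusted p = 1.58e-06, and 0.0361 with an estimated correlation).

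In TLR4 null kidneys Il6 rose by 2.97 ± 0.37, Cxcl2 by 3.09 ± 0.23, Ccl2 by 1.06 ± 0.22, Hbegf by 2.85 ± 0.16 and Icam1 by 0.93 ± 0.11. The selectins Sele (1.24 ± 0.39, adjusted p = 0.0343) and Selp (0.79 ± 0.22, adjusted p = 0.0184) rose, and Vcam1 did not pass (0.24 ± 0.17, adjusted p = 0.391). The counts were 6 of 13 cytokines and growth factors (6 adjusted over the list alone), 8 up and 1 down of 16 NF-kB genes (11 and 1 adjusted over the list alone) and 10 of 15 endothelial activation genes (11 adjusted over the list alone). These 3 lists passed camera with the preset and with the estimated correlation (adjusted p = 0.0113, 0.0175 and 0.0113 with an estimated correlation). Chemokines (5 up and 1 down of 13, the same adjusted over the list alone), acute phase genes (8 up and 2 down of 18, 9 and 3 adjusted over the list alone), proposed TLR4 ligands (6 up and 1 down of 12, 6 and 3 adjusted over the list alone) and neutrophil markers (3 up of 9, 3 adjusted over the list alone) passed with the preset correlation. Those calls were lost (adjusted p = 0.0829, 0.26, 0.26 and 0.196 with an estimated correlation). Of 15 endothelial cell markers, 7 fell and 1 rose (8 and 1 adjusted over the list alone), with Tek at -1.28 ± 0.13 and the endocytic protein Ehd3 at -0.74 ± 0.12.

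Fatty acid oxidation and PPARA targets fell in 11 of 15 cases in TLR4 null kidneys (13 adjusted over the list alone, camera adjusted p = 1.54e-08, and 0.0225 with an estimated correlation), with Cpt2 at -1.19 ± 0.10 and the peroxisomal enzyme Ehhadh at -1.19 ± 0.13. Of 23 proximal tubule transporters, 10 fell (11 adjusted over the list alone), among them Slc5a12 (-0.74 ± 0.09), Slc22a2 (-0.54 ± 0.09) and the endocytic receptor Lrp2 (-0.52 ± 0.10), while Slc34a1 was at -0.06 ± 0.11. Of 17 loop, distal tubule and collecting duct genes, 7 fell (9 adjusted over the list alone), with Kcnj1 at -0.95 ± 0.09. The calls of both tubular lists (adjusted p = 3.33e-05 and 6.82e-04) were lost (adjusted p = 0.278 and 0.259 with an estimated correlation). Adipoq ranged from 34.8 to 801.3 on these 3 ischemic arrays, and no fat marker passed. Of the other lists, 1 of 15 interferon-stimulated genes fell, Usp18 (-0.58 ± 0.19, 0 adjusted over the list alone), and of 18 Toll-like receptors and adaptors Cd14 (0.79 ± 0.16) and Tollip (0.31 ± 0.09) rose and Irak1 fell (-0.81 ± 0.25, adjusted p = 0.0313), a call lost with probe sets of the suffixes _x_at and _s_at left out. Besides, 6 of 20 hypoxia-inducible genes rose and 5 fell, and 6 of 17 clock genes rose and 2 fell (7 and 3 adjusted over the list alone). None of these 4 lists passed camera.

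**Figure D2:**
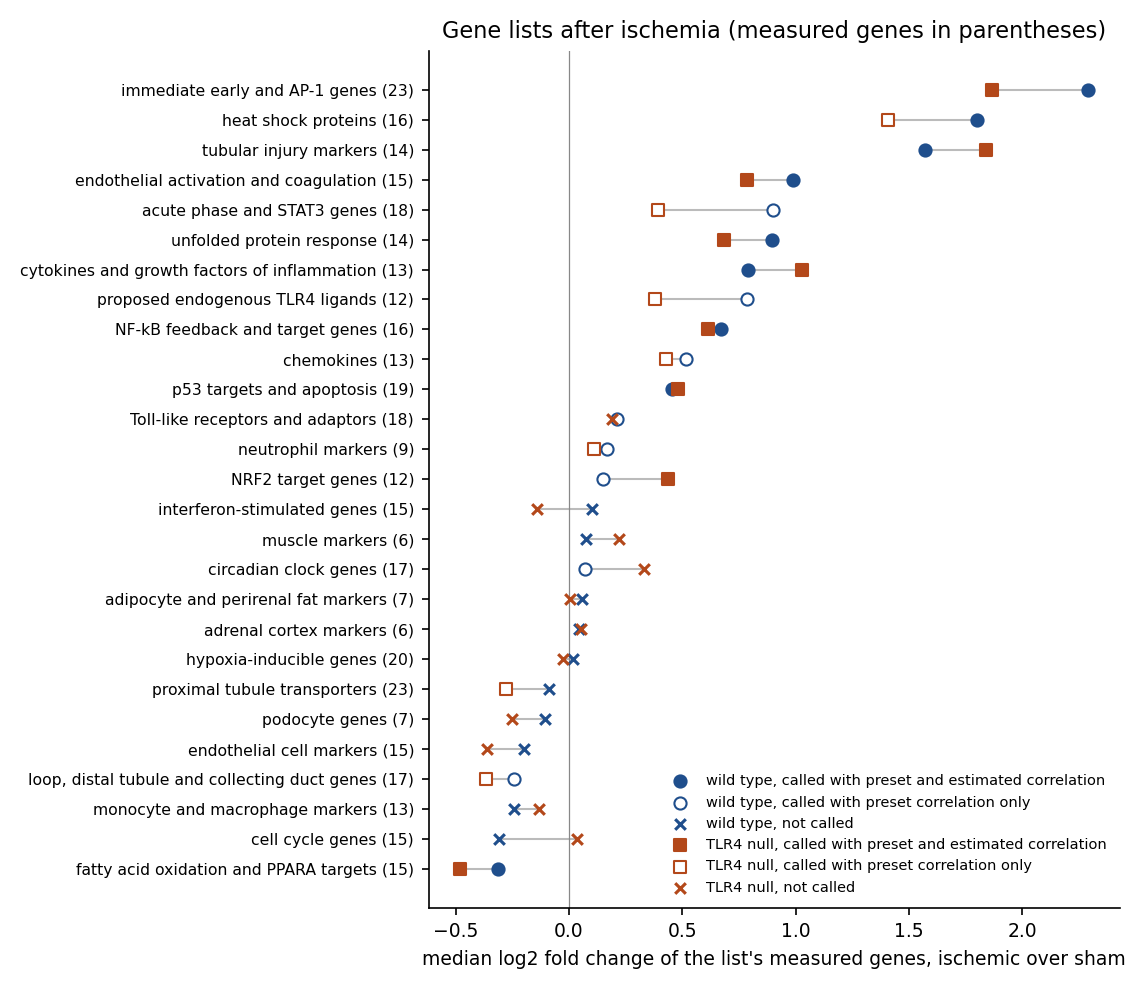
Median log2 fold change, ischemic over sham, of the measured genes of 27 fixed lists in wild type (circles) and TLR4 null (squares), filled where the list passed camera with both correlations, open where it passed with the preset correlation only, and crosses where it did not pass. The immediate early list lies highest in both genotypes, at 2.29 and 1.87.

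Of the 2814 genes called in wild type and 3088 in TLR4 null, 1931 were called in the same direction in both, 999 higher and 932 lower, where independent lists would share 129 and 176. Only 4 were called in opposite directions, Rpl27a (-0.72 ± 0.19 in wild type and 0.74 ± 0.19 in TLR4 null), AU040972, 1810014B01Rik and 4932431P20Rik, which are named here after their values were seen. None of them passed the interaction test below. Log2 fold changes correlated at r = 0.726 across all 14322 genes, which are not independent replicates, and 96.9% of the genes called in wild type had the same sign in TLR4 null kidneys, with a slope of 0.85 of the TLR4 null on the wild-type change. These genes were picked by their wild-type change, which lowers the slope, and it was not tested. The 2 comparisons share no array, but they share 1 model and its estimate of each gene's spread. Their calls are thus not independent, and the expected 129 and 176 are only a rough guide. List calls that hold with an estimated correlation in both genotypes are those of immediate early genes, cytokines, NF-kB genes, endothelial activation, tubular injury, p53 targets, the unfolded protein response and fatty acid oxidation. Heat shock proteins held in wild type alone and NRF2 targets in TLR4 null alone, and the interaction of these 2 lists had medians of -0.58 and 0.15 (adjusted p = 0.726 for each with an estimated correlation).

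**Figure D3:**
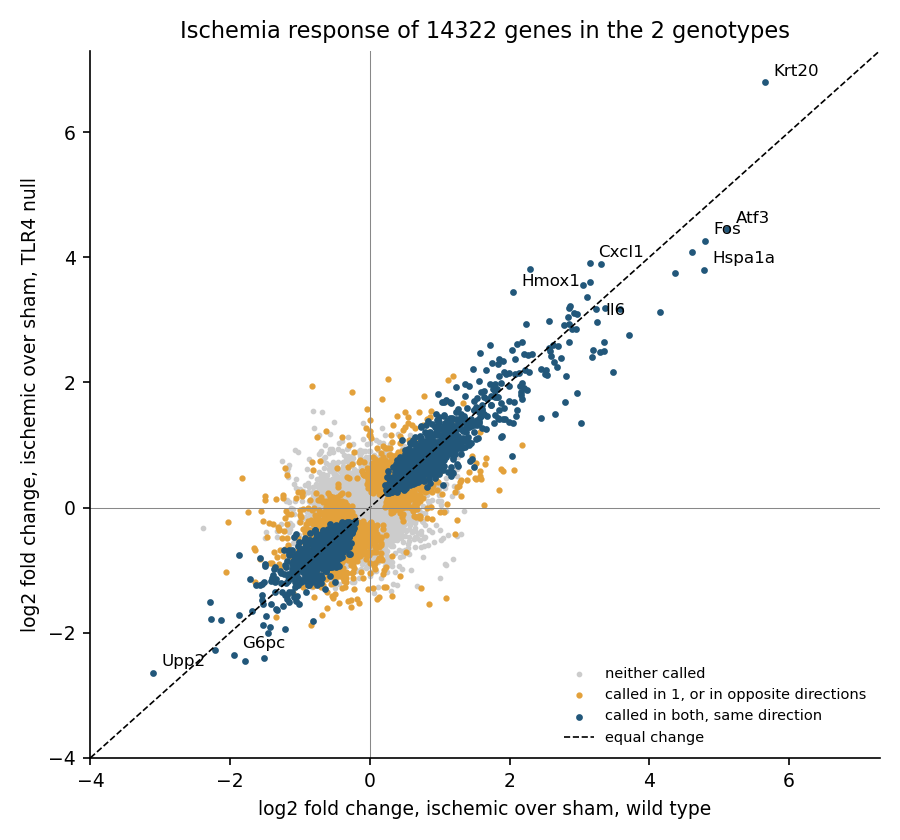
Log2 fold change, ischemic over sham, in wild type (x axis) and TLR4 null kidneys (y axis) for 14322 genes. Blue points are the 1931 genes called in the same direction in both, orange points the other called genes and grey points the rest, and the dashed line marks equal change.

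No gene had an ischemia response that passed the test for a difference between the genotypes. In limma 0 of 14322 genes passed for the genotype by surgery interaction. The smallest adjusted p was 0.244, and 913 genes had an unadjusted p under 0.05, where 716 are expected by chance. The 5 named genes with the smallest p, none of which passed, were the lipoprotein component Apoc3 (0.99 ± 0.16, TLR4 null response minus wild-type response), Prepl (1.23 ± 0.22), the ribosomal protein Rpl27a (1.46 ± 0.27), the microtubule-binding protein Mapre2 (0.64 ± 0.12) and the ubiquitin-conjugating enzyme Ube2n (0.81 ± 0.16). For genes of inflammation and injury the differences and their SEs were -0.28 ± 0.52 for Il6, 0.76 ± 0.36 for Cxcl1, 0.13 ± 0.32 for Cxcl2, 0.33 ± 0.31 for Ccl2, -0.28 ± 0.16 for Icam1, -0.28 ± 0.24 for Vcam1, 0.25 ± 0.55 for Sele, 0.19 ± 0.31 for Selp, 0.41 ± 0.35 for Lcn2, 0.34 ± 0.75 for Havcr1, -0.67 ± 0.47 for Atf3 and 1.39 ± 0.74 for Hmox1, with adjusted p from 0.783 (0.76, Cxcl1) to 0.969 (0.13, Cxcl2). Selp, Sele and Havcr1, which passed in TLR4 null kidneys alone, and Vcam1, which passed in wild type alone, are thus not shown to differ. With these spreads, simulated interactions of 1 and 2 log2 units were recovered for 50.7% and 84.8% of changed genes and those of 0.5 for 13.4%. The simulated genes varied independently, without shifts shared by the genes of an array. They were drawn with the spreads that limma had already pulled toward each other, and 200 genes were changed at once. Recovery in the real data may thus differ, and with fewer true interactions it may be lower. Without TLR4 null ischemic replicate 3, 15 genes passed, 10 higher and 5 lower, led by Rpl27a.

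As groups, 6 of 27 lists had smaller or more negative responses in TLR4 null kidneys by camera with the preset correlation. Heat shock proteins had a median difference of -0.58 (adjusted p = 2.09e-07), proposed endogenous TLR4 ligands of -0.37, interferon-stimulated genes of -0.27, proximal tubule transporters of -0.19, immediate early genes of -0.19 and fatty acid oxidation genes of -0.14. All 6 calls were lost (adjusted p = 0.726 with an estimated correlation). The TLR4 null ischemic arrays behind these differences stand apart in the 18S 3' control probe set, which differed from sham by 2.31 ± 0.24 in TLR4 null and by 0.48 ± 0.24 in wild type. Within those lists, Hsp90aa1 was at -0.69 ± 0.16, Hsph1 at -1.13 ± 0.39, Egr2 at -1.02 ± 0.33, Oasl2 at -0.67 ± 0.28, Slc13a3 at -0.75 ± 0.19 and Ehhadh at -0.69 ± 0.18. Over all genes no member passed. Adjusted over the list alone, 1 member each of the heat shock, proximal tubule and fatty acid lists passed as lower and none of the other 3 lists. Among lists that camera did not call, 1 tubular injury marker, 2 NRF2 targets and 1 p53 target passed as higher when adjusted over the list alone.

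**Figure D4:**
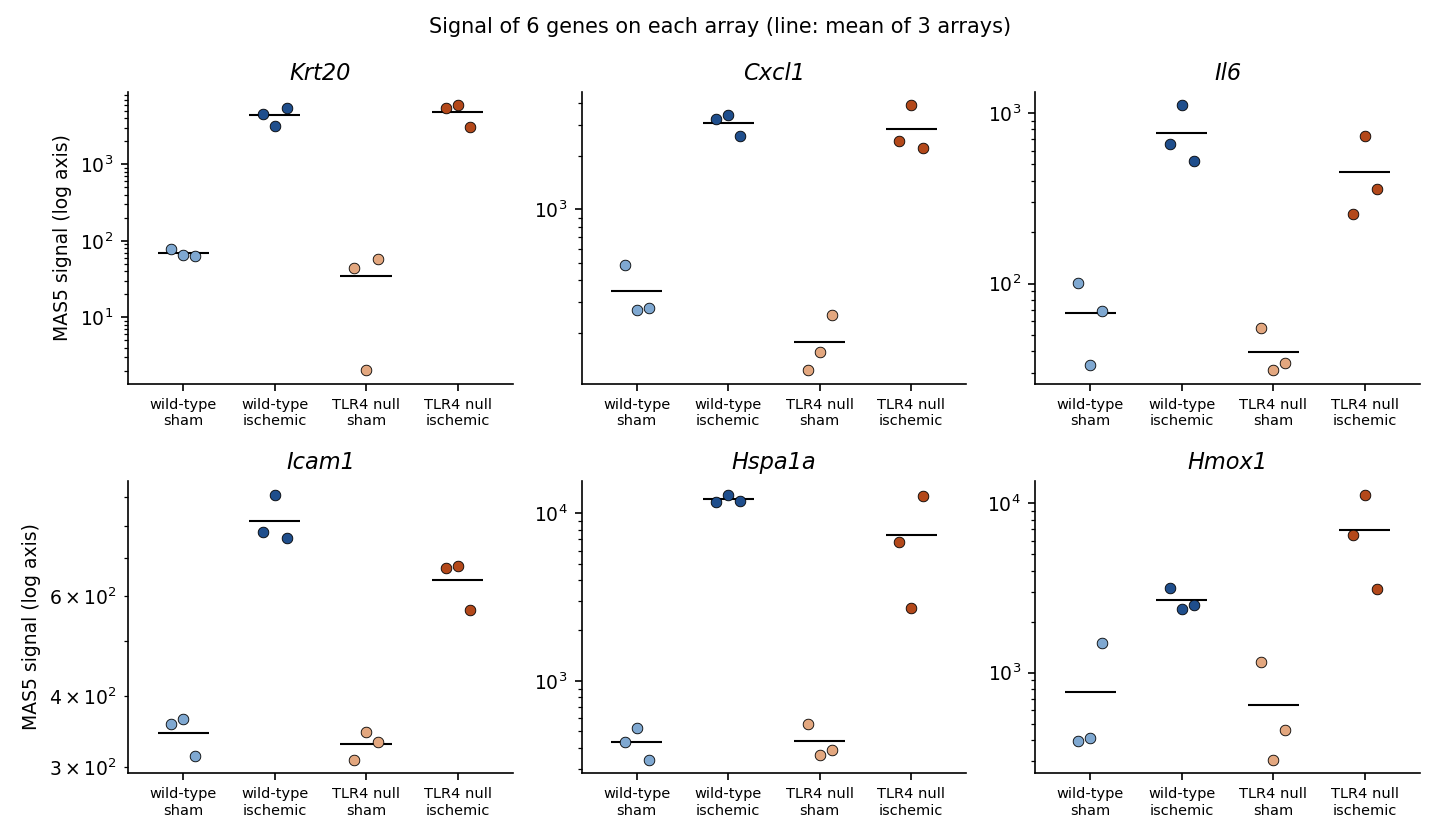
Signal of 6 genes (linear MAS5 units, log axes) on each of the 12 arrays by group, where points are arrays and lines are group means of 3 arrays. Every ischemic array lies above every sham array of its genotype for each gene, and the TLR4 null ischemic arrays spread from 2709.6 to 12724.1 for Hspa1a.

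Between sham kidneys of the genotypes, genes of cell division were lower in TLR4 null. Mki67, a marker of dividing cells, gave a signal of 167 ± 18.2 in wild type and 11.3 ± 6.02 in TLR4 null sham kidneys (-2.81 ± 0.25, limma adjusted p = 1.82e-04). The mitotic kinase Cdk1 differed by -2.40 ± 0.40, the mitotic protein Birc5 by -2.38 ± 0.37, the helicase Ercc6l by -2.00 ± 0.31, cyclin B2 (Ccnb2) by -1.58 ± 0.27 and the collagen Col1a1 by -1.83 ± 0.35. The amino acid transporter Slc7a12 (-1.69 ± 0.30), the carboxylesterase Ces1g (-1.64 ± 0.21) and Lcn2 (-1.48 ± 0.25) were lower too. Higher in TLR4 null sham kidneys were Cyp2b10 (1.54 ± 0.30), Azgp1, a secreted glycoprotein (1.51 ± 0.21), Cyp4a12a (1.31 ± 0.22), the peptidase Cpe (0.96 ± 0.18), the small GTPase Arf5 (0.85 ± 0.12), the dicarboxylate transporter Slc13a3 (0.80 ± 0.13), Slco1a6 (0.56 ± 0.11) and the adhesion molecule Cadm1 (0.52 ± 0.10). In all, 45 of 14322 genes passed, 13 higher and 32 lower. The count was unstable. It was 2, 4 and 37 without wild-type sham replicates 1, 2 and 3, and 9, 18 and 5 without TLR4 null sham replicates 1, 2 and 3. Fewer arrays in a group also make it harder for a gene to pass, but each of these fits drops 1 array and their counts differ widely. Genes at an unadjusted p under 0.05 were fewest without wild-type sham replicate 2. They numbered 928 there, against 1252 and 1120 without replicates 1 and 3 and 1339 with all arrays. Most of the 45 genes had their highest adjusted p without that replicate, so the calls lean on it more than on other arrays. Only Mki67 and Ces1g passed in each of the 12 fits that leave out 1 array.

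Of 15 cell cycle genes, 5 were lower in TLR4 null sham kidneys over all genes and 11 adjusted over the list alone, and all 15 had lower means (median -0.72, camera adjusted p = 4.42e-16, and 0.0302 with an estimated correlation). Besides Mki67, Cdk1 and Birc5 these were Top2a (-1.48 ± 0.22) and Rrm2 (-1.38 ± 0.20), both enzymes of DNA metabolism. Camera with the preset correlation called 11 more lists lower, among them tubular injury markers (1 of 14 lower, 7 adjusted over the list alone, median -0.45), interferon-stimulated genes (0 of 15, 1 adjusted over the list alone, median -0.39), acute phase and STAT3 genes (1 of 18, 5 adjusted over the list alone, median -0.38) and monocyte and macrophage markers (0 of 13 by either count, median -0.29). It called 2 lists higher, proximal tubule transporters (1 of 23, 5 adjusted over the list alone, median 0.19) and fatty acid oxidation genes (0 of 15 by either count, median 0.09). Only the cell cycle call held otherwise (the next lowest adjusted p = 0.0745 with an estimated correlation, for the tubular injury markers). The fat marker list was lower (median -0.86, adjusted p = 0.0302, and 0.465 with an estimated correlation), with no member past the test, and the mean log2 value of its 7 genes was 9.39 ± 0.438 (SD) in wild-type and 8.56 ± 0.528 in TLR4 null sham kidneys.

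Between ischemic kidneys of the genotypes, Mki67 was lower in TLR4 null (-1.84 ± 0.25, limma adjusted p = 0.00483), as were Cdk1 (-1.87 ± 0.40), Shcbp1 (-1.92 ± 0.32) and the fibrillar collagens Col3a1 (-1.85 ± 0.23, from 1687 ± 574 to 451 ± 123) and Col1a1 (-1.84 ± 0.35). Cyp27b1, the renal enzyme that activates vitamin D, differed by -2.34 ± 0.36, the apelin receptor Aplnr by -2.31 ± 0.46, Fam167b by -2.10 ± 0.41 and the alarmin cytokine Il33 by -0.91 ± 0.12. Higher in TLR4 null were Erdr1 (2.05 ± 0.25), Cep128 (1.54 ± 0.31), Azgp1 (1.42 ± 0.21), Lncppara (1.33 ± 0.29), Arf5 (0.97 ± 0.12), Prepl (0.93 ± 0.15), the plasma glycoprotein Apoh (0.92 ± 0.14) and Mtg2 (0.90 ± 0.19). In all, 94 genes passed, 20 higher and 74 lower. The TLR4 null ischemic arrays also stand apart in the 18S 3' control probe set (2114 ± 636 against 550 ± 21.4 in wild-type ischemic kidneys, SD), and whether they were processed in a batch of their own is not given in the sources used here. Without 1 array the count was 10 (wild-type ischemic replicate 3), 47 and 58 (wild-type ischemic replicates 2 and 1), 43, 48 and 245 (TLR4 null ischemic replicates 1, 2 and 3), and 66 to 93 without a sham array. Passing in all 12 such fits were 9 genes, Aadat, Arf5, Col3a1, Erdr1, Il33, Mgp, Mki67, Sparc and Tmsb10.

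Of 15 cell cycle genes, 4 were lower in TLR4 null ischemic kidneys (9 adjusted over the list alone, median -0.80, camera adjusted p = 5.18e-10, and 0.0701 with an estimated correlation). Of 15 interferon-stimulated genes, 3 were lower (8 adjusted over the list alone, median -0.62, adjusted p = 1.45e-10, and 0.0985 with an estimated correlation), the antiviral genes Rsad2 (-1.22 ± 0.22), Oasl2 (-0.99 ± 0.20) and Ifih1 (-0.91 ± 0.19). Of the 12 fits that leave out 1 array, Rsad2 passed in 9, Oasl2 in 6 and Ifih1 in 1. The interferon list's mean log2 value was 7.74, 7.70 and 8.25 in wild-type ischemic replicates 1, 2 and 3, so replicate 3 enlarges the difference. It was at most 7.47 in TLR4 null ischemic kidneys. Acute phase and STAT3 genes had 1 lower of 18 (9 adjusted over the list alone, median -0.60), the fibrinogen chain Fgg (-0.91 ± 0.19), and the serum amyloid Saa3 was at -1.66 ± 0.38 (adjusted p = 0.059). In wild-type ischemic replicates 1, 2 and 3, Saa3 gave 475.8, 197.4 and 705.7. The list's mean log2 value was 9.64, 9.01 and 9.94 there, and that of the 7 fat markers 10.12, 7.67 and 10.22. Acute phase and fat marker levels thus moved together on these arrays, and replicates 1 and 3 enlarge the difference. TLR4 null ischemic replicate 1, with a fat marker value of 10.13, had a list value of 8.76, below all 3 wild-type values. Proposed TLR4 ligands had 1 lower of 12 (7 adjusted over the list alone, median -0.58), fibronectin (Fn1, -0.74 ± 0.14). Endothelial activation genes had 1 lower of 15 (4 lower and 1 higher adjusted over the list alone), thrombomodulin (Thbd, -0.66 ± 0.13), and endothelial cell markers 1 lower of 15 (5 adjusted over the list alone), Ehd3 (-0.60 ± 0.12). Of the 12 fits that leave out 1 array, Fgg passed in 1, Ehd3 in 2, Fn1 in 6 and Thbd in 9. Among 13 monocyte and macrophage markers, the complement component C1qa was lower (-0.64 ± 0.13), also adjusted over the list alone. No heat shock protein passed over all genes (8 lower adjusted over the list alone, median -0.48), nor any immediate early gene (8 lower adjusted over the list alone, median -0.44). Among 12 NRF2 targets Nqo1, a quinone reductase, was higher (0.62 ± 0.12), with 3 higher adjusted over the list alone. Camera with the preset correlation called 13 lists lower and 1 (NRF2 targets) higher, and none held (lowest adjusted p = 0.0701 with an estimated correlation, for the cell cycle genes and the proposed TLR4 ligands). The fat marker list was again lower (median -1.05, adjusted p = 0.0193, and 0.432 with an estimated correlation), and 56 genes passed with the fat score of each array in the model.

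Both genotype comparisons, which share no array, called 19 genes in common, all in the same direction, 4 higher and 15 lower, where independent lists would share 0.0182 and 0.165. The comparisons do share 1 model and its estimate of each gene's spread. Their calls are thus not independent, and the expected counts are only a rough guide. Across all genes the log2 differences correlated at r = 0.223. Higher in TLR4 null kidneys of both surgeries were Arf5, Azgp1, Cadm1 and the transcription factor Foxo1 (0.47 ± 0.09 in sham and 0.46 ± 0.09 in ischemic kidneys). The 15 lower genes were the proliferation genes Cdk1, Mki67, Pbk (-1.45 ± 0.21 and -0.99 ± 0.21), Rrm2 and Top2a, the matrix genes Col1a1, Col3a1, Col4a1 (-0.65 ± 0.12 and -0.75 ± 0.12), Col4a2 (-0.65 ± 0.10 and -0.56 ± 0.10), Col6a3 (-0.72 ± 0.12 and -0.63 ± 0.12) and Sparc (-0.86 ± 0.14 and -1.05 ± 0.14), the platelet chemokine Pf4 (-0.73 ± 0.14 and -0.84 ± 0.14), Tmsb10 (-0.65 ± 0.11 and -0.74 ± 0.11), Ces1g and Cyp2d26 (-0.55 ± 0.10 and -0.55 ± 0.10). Mki67 gave 128.1 to 188.0 on the 6 wild-type arrays and 6.82 to 38.6 on the 6 TLR4 null arrays, and Col3a1 gave 1197.6 to 2319.1 and 309.2 to 710.0. The mean log2 value of the 15 cell cycle genes was lower by 0.87 ± 0.10 (SE) in TLR4 null kidneys, with all 6 TLR4 null arrays below all 6 wild-type arrays (exact permutation p = 0.005 over 400 arrangements within surgery, two-sided, the smallest possible), a test chosen after the list was seen lower and not adjusted over the 27 lists. The same full separation, lower in TLR4 null, held for 3 other lists, interferon-stimulated genes (lowest wild-type array 7.69, highest TLR4 null array 7.51), monocyte and macrophage markers (7.59 and 7.55) and, by the smallest gap, hypoxia-inducible genes (9.554 and 9.551). The genotypes are separate substrains, and this design does not tie these differences to Tlr4.

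**Figure D5:**
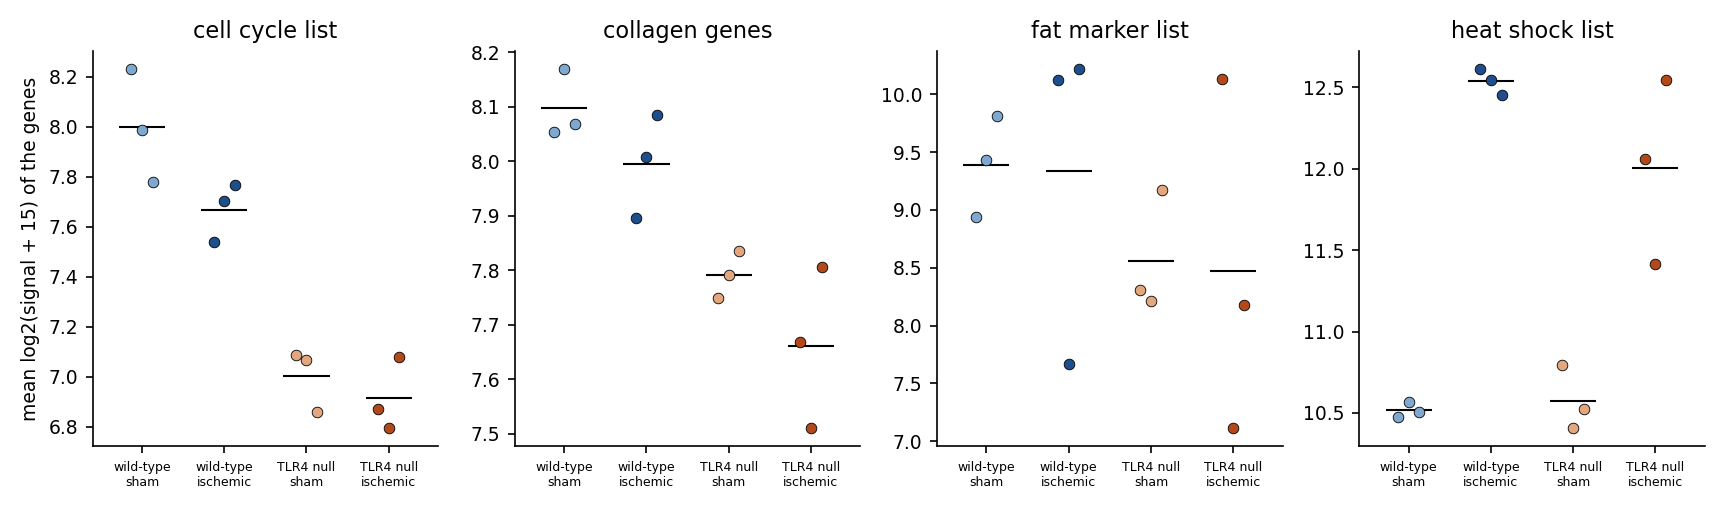
Mean log2 value per array of the cell cycle list (15 genes), the collagen genes (33), the fat marker list (7) and the heat shock list (16), by group, where points are arrays and lines are group means of 3 arrays. Cell cycle scores of TLR4 null arrays reach at most 7.09, where the lowest wild-type array has 7.54.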

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

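The list tests with both correlations and the predictions for regrouped arrays were fixed before the data were examined, while the tests of explanations, the quality tests of the 18S probe sets beside them and the regrouping test of the interaction's count of 0 were chosen only after the result was seen. The responses to ischemia of 6 lists differed between the genotypes by limma's camera with a preset correlation, as median interactions of -0.19 for immediate early genes, -0.37 for proposed endogenous TLR4 ligands, -0.58 for heat shock proteins, -0.27 for interferon-stimulated genes, -0.19 for proximal tubule transporters and -0.14 for fatty acid oxidation genes. None of the 6 differences passed with an estimated correlation (adjusted p = 0.726).

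The smaller rise of heat shock proteins in TLR4 null kidneys might come from a weaker injury of those kidneys as a whole or from a single array. The tubular injury list had an interaction of 0.17 ± 0.17 (SE), so its rise was not smaller in TLR4 null, but this lies only just past the bound of 1 SE and the list's level was lower in TLR4 null sham (median -0.45) and ischemic kidneys (median -0.32), so a weaker injury stays open. The mean interaction of the heat shock list was -0.58 ± 0.35 with all arrays, -0.29 ± 0.21 without TLR4 null ischemic replicate 2 and -0.85 ± 0.25 without TLR4 null ischemic replicate 3. Its weakest value relative to its SE was -0.48 ± 0.38, without TLR4 null sham replicate 1, so it kept its sign but under a weak bound. A genotype effect on the heat shock response could remain, but with an estimated correlation the list does not pass, and the value of -0.29 ± 0.21 shows how far it rests on replicate 2.

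The 18S 3' control probe set, which no comparison uses, gave 3.85 times the signal in TLR4 null ischemic kidneys as in wild-type ischemic kidneys, with 2287.2, 2645.9 and 1410.4 on those 3 arrays. Over both genotypes the ischemic arrays were higher than the sham arrays (6 against 6, exact permutation p = 0.00216, two-sided, 0.0303 adjusted over 14 quality tests). Degraded RNA might raise 3' signals, but the actin 3' over 5' ratio of the TLR4 null ischemic arrays was 1.86 ± 0.142 (SD), against 1.92 in wild-type ischemic kidneys. More 18S RNA along its whole length might do so as well, but the middle probe set differed by 0.22 ± 0.09 (SE) and the 3' probe set by 1.87 ± 0.24. The cause stays open, and no biological explanation was tested.

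Lower cell division genes and collagens in TLR4 null kidneys could come from perirenal fat left on the kidneys or from the scaling between arrays. With the fat score in the model, the difference in the cell cycle list's mean was -0.91 ± 0.11 (SE) and that of the collagen genes -0.30 ± 0.06. Under the scaling that gave the smaller difference, the values were -0.86 ± 0.10 and -0.31 ± 0.06. Neither explanation removes the differences, and a difference between the substrains, at Tlr4 or elsewhere in the genome or in how the mice were kept or the arrays processed, was not tested.

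Probe sets without a single gene name, which the report leaves out, were called in 473 cases for ischemia in wild type and in 464 for ischemia in TLR4 null. Regrouping the 6 arrays of a comparison gives 10 splits, too few for a share under 0.05. For ischemia in wild type 1 of 10 splits, the real one, called as many as the real 2814 genes (highest other 0), for ischemia in TLR4 null 1 of 10 (3088, highest other 1), for genotype in sham kidneys 1 of 10 (45, highest other 1) and for genotype in ischemic kidneys 1 of 10 (94, highest other 19). For the interaction, 100 of 100 regroupings called at least the real 0 genes (highest other 301). Any regrouping must do so, and that count carries no information. At an unadjusted p under 0.05, 17 of 100, the real grouping among them, had at least the real 913 genes (highest other 1921). Genotype was regrouped in each surgery separately, so genotype differences common to both surgeries enter the regrouped interactions. These regroupings thus do not show what an absent interaction would give, and the 17 of 100 decides nothing.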

How the results depend on the processing

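The fat score covariate and the count of calls that hold without each array were chosen only after the result was seen. The 0 called genes of the interaction stayed 0 in every alternative run for it (the 2-group fit and the ordinary test do not apply) except without TLR4 null ischemic replicate 3 (range 0 to 15 over the 12 fits that leave out 1 array). The counts for ischemia stayed within 1.5 times except with an ordinary equal-variance test per gene, which does not share spread between genes (1684 in wild type and 864 in TLR4 null). Median normalization gave 1955 in wild type, 65.9% of them higher against 46.7% as deposited, and 2212 in TLR4 null, 53.3% higher. So the balance of rises and falls depends on scaling. The 45 genes that differed by genotype in sham kidneys became 20 with median normalization, 4 without the variance trend, 160 with array weights, 81 with only the 2 groups compared, 0 with the ordinary test, and 2 to 61 without 1 array. The 94 in ischemic kidneys became 47 with no filter, 20 without the variance trend, 164 with array weights, 61 with the replicate block, 56 with the fat score, 17 with only the 2 groups, 0 with the ordinary test, and 10 to 245 without 1 array. For these the cause was not tested. Called in every fit without 1 array were 1635 of 2814, 1858 of 3088, 2 of 45 and 9 of 94 genes. The 1931 shared calls became 1155 at an adjusted p under 0.01 and 320 with a 2-fold change, by construction. Irak1 in TLR4 null ischemia reversed without _x_at and _s_at probe sets (0.0337, adjusted p = 0.84, against -0.81), since another probe set then stands for it. Among 1608 alternatives of 67 called lists, 1469 were the same, 139 weaker and 0 reversed, and 48 of 67 lists lost their call with an estimated correlation. Among 15045 alternatives of 658 gene values, 14322 were the same, 478 weaker, 127 stronger, 117 moved and 1 reversed. Replicate numbers do not pair the arrays: 1 of 18 same-number pairs correlated above 0.1 (-0.06 to 0.10), and 6 of 18 were best with their own number. The block left 33 sham genotype calls. Signals near background limit the log2 values of dim genes.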

Other observations

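The 13 gene families of this part, and the genes named from them, were chosen only after the result was seen. Of 16 measured aminoacyl-tRNA synthetases, which charge tRNAs for protein synthesis, 9 rose after ischemia in wild type (median 0.50) and 10 in TLR4 null (median 0.61), among them Aars (1.12 ± 0.14 and 1.02 ± 0.14), Yars (0.87 ± 0.16 and 1.03 ± 0.16), Nars (0.80 ± 0.13 and 0.70 ± 0.13) and Tars (0.88 ± 0.20 and 0.79 ± 0.20). The family passed limma's camera with the preset correlation (adjusted p = 8.40e-06 and 1.21e-06) and not otherwise (adjusted p = 0.211 and 0.162 with an estimated correlation). Among 21 dual specificity phosphatases, some of which switch off MAP kinases, 8 rose in wild type, led by Dusp5 (3.15 ± 0.23) and Dusp14 (2.95 ± 0.15). In TLR4 null kidneys 6 rose and 1 fell, with Dusp8 at 1.88 ± 0.21 and Dusp14 at 2.85 ± 0.15. Camera called these phosphatases with the preset correlation (adjusted p = 0.00149 in wild type and 0.00246 in TLR4 null). Both calls were lost (adjusted p = 0.161 and 0.162 with an estimated correlation).

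Of 34 measured subunits of respiratory complex I, 6 fell in wild type (median -0.18) and 15 in TLR4 null (median -0.22), with Ndufb8 at -0.31 ± 0.07 and -0.33 ± 0.07 and Ndufs7 at -0.29 ± 0.08 and -0.27 ± 0.08. The family passed camera with the preset correlation (adjusted p = 0.00149 and 9.35e-06) and not otherwise (adjusted p = 0.497 and 0.352 with an estimated correlation). Among 302 solute carriers 25 rose and 66 fell in wild type, and 23 rose and 75 fell in TLR4 null. With the preset correlation, camera did not call them in wild type (adjusted p = 0.0750) and did in TLR4 null (adjusted p = 0.0142). Neither passed with an estimated correlation (adjusted p = 0.433 and 0.278). The 33 collagen genes had no rise and 5 falls in TLR4 null against wild-type sham kidneys (median -0.34) and 10 falls in ischemic kidneys (median -0.29). This family was formed after collagens were seen among the called genes of these comparisons, so its test on the same arrays adds nothing to those calls.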
